A study of Homo sapiens with 2 samples.

How the data were processed

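Gene expression was measured on Affymetrix oligonucleotide arrays in MDA-MB-231 cells, a mesenchymal-like human breast cancer line without oestrogen receptor, progesterone receptor or HER2 amplification. Per the labels' protocols, siRNA transfection lasted 48 hours, RNA was isolated with the ISOGEN reagent, and biotinylated cRNA was made from 150 ng of it. The labels give 2 groups with 1 array each, cells given a control siRNA and cells given an siRNA against NONO. They do not say whether 1 or several siRNA sequences were used.

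The deposited values are on a log2 scale, as judged from their range of 1.80 to 13.98. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, a procedure that corrects background, quantile-normalizes arrays and summarises the probes of a probe set by median polish. Software versions, library files and the genome build are not given in the sources used here. Quantile normalization forces the arrays to nearly the same distribution, so a change in total RNA per cell cannot be seen, and RMA tends to compress differences of dim probe sets. Both deposited columns had a median of 5.83, and their sorted values differed by at most 0.078. No scanner values, detection calls or probe-level values were used here, so whether a probe set was above background is unknown, and the precision is limited by the number of arrays.

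Of 33297 probe sets, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 had none. Gene names were taken from that annotation through its Entrez gene identifiers. Of the single-gene probe sets, 19429 were found in the RefSeq gene table for GRCh38.p14, which changed no symbol. Coordinates are not printed, because no build is named for the files. The single-gene probe sets stood for 18417 genes. Of these, 769 genes had several probe sets, and the one with the highest mean of both arrays was used.

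A gene was kept when the mean of both arrays reached 6.47, the median over single-gene probe sets, which left 9253 genes. The difference is the log2 value after NONO siRNA minus that after control siRNA. With 1 array per group there is no replicate check and no p-value, and a fixed size of 2-fold was used instead, or 1.5-fold for members of gene lists. "Higher" and "lower" therefore describe these arrays only.

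The 21 gene lists, the filter, the sizes and the naming rule were fixed before the data were examined. The named genes are NONO, SFPQ, PSPC1, SKP2 and E2F8, the 12 highest and 12 lowest differences after the filter (uncharacterised loci, small RNAs and pseudogenes are counted but not named), and up to 2 highest and 2 lowest members of each list. Any other gene named was chosen after its value was seen. SKP2 and E2F8 have been reported as NONO-regulated in breast cancer cells. For that reason they were placed on the naming rule and in the list of S phase genes, and they are not independent evidence for that list. Whether those reports rest on these same arrays is not known here, so their values are not read as agreement with other work. Older and newer symbols of a gene were counted once. NONO was left out of the median of its own list, and 14 genes belong to more than 1 list.

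For each list of at least 5 members after the filter, the median difference was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart when its median lay outside the central 95% of those medians, called the random range below. Genes of a list are often co-regulated, so such percentiles describe these arrays and are not tests of the treatment. Of the 20 lists with a percentile, about 1 would stand apart by chance if the genes within a list varied independently of each other. Co-regulated genes do not, so more lists than that can stand apart by chance.

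The calculations were tested on simulated data built from the 9253 genes of this comparison. Of 200 genes changed 3-fold, 99.5% passed 2-fold and 0 unchanged genes did, at a normal spread set from the observed differences. That spread was 0.204, while the observed differences had an SD of 0.27. With a normal spread so far below 2-fold, a count of 0 was nearly certain in advance. It therefore does not give the rate at which unchanged genes pass 2-fold on these arrays. With permuted differences, 6.2% of 400 lists of 30 genes stood apart without a shift, 68.0% of 100 lists did so with a shift of 0.1 and 100.0% with a shift of 0.2.

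The alternatives were no filter, a filter at the 75th percentile, the mean of a gene's probe sets, genes with 1 probe set only, centring each array on its median, a loess fit of the difference on the mean (span 0.3), thresholds of 1.5-fold and 3-fold, and random lists in 5 bins or unmatched. Gene length was planned as a further comparison and was not run, since the gene table belongs to an assembly that the files do not name. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.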

Results

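The arrays address which transcripts differ in MDA-MB-231 cells when NONO is depleted. NONO is an RNA- and DNA-binding protein of the DBHS family (with SFPQ and PSPC1) that is found in nuclear paraspeckles. Cells given control siRNA and cells given NONO siRNA were each measured on 1 array, 48 hours after transfection. Every value below is a single log2 signal, so no replicate error can be given, and no difference has been tested against variation between cultures. The arrays correlated at r = 0.9938 across all 33297 probe sets, which are not independent replicates. Over the 9253 genes above the filter on dim signals the median difference was -0.002, and the central 95% of differences ran from -0.61 to 0.48.

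NONO itself was lower in the cells given NONO siRNA. Its single probe set (8168280, Entrez gene 4841) read 11.13 with control siRNA and 9.58 with NONO siRNA, a difference of -1.55 or 2.93-fold, the rank of 7 from the bottom among 9253 genes. Its signal after NONO siRNA was thus 34.2% of the control signal. The transcripts of the other DBHS family members were somewhat higher, PSPC1 by 0.47 (9.06 to 9.53) and SFPQ by 0.28 (10.35 to 10.64). Both lay inside the central 95% of all genes, PSPC1 close to its upper end of 0.48. None of the 32 paraspeckle components and NONO partners above the filter differed by 1.5-fold, and their median was -0.015. The extremes after PSPC1 were FIGN at 0.30, and HNRNPUL1 at -0.38 and HNRNPF at -0.27.

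Few genes differed strongly. Of 9253 genes, 74 (0.8%) differed at least 2-fold, 25 of them higher and 49 lower after NONO siRNA. At 1.5-fold the counts were 141 higher and 260 lower, and at 3-fold 2 higher and 4 lower. The predominance of lower genes was smaller without the filter, where 45 genes were higher and 57 lower. It was larger with the filter at the 75th percentile, where 10 were higher and 29 lower.

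The highest difference was that of FERMT1, which encodes the integrin activator kindlin-1 and was 4.84-fold higher (7.83 to 10.10 on the log2 scale). MAL2, a protein of apical transport in polarised epithelia, was 2.89-fold higher, and ITGB4, the integrin subunit of hemidesmosomes, 2.38-fold higher. GJA1, a connexin of gap junctions, was 2.28-fold higher. The adhesion receptor ADGRF1 was 3.23-fold higher, the sphingosine-1-phosphate transporter SPNS2 2.88-fold, the cytokine TNFSF15 2.69-fold, the G-protein regulator RGS4 2.66-fold and the D-type cyclin CCND2 2.33-fold. The ectonucleotidase ENTPD3 was 2.55-fold and the urea transporter SLC14A1 2.30-fold higher. The control values of ENTPD3 (5.87), SPNS2 (5.96), GJA1 (6.03) and SLC14A1 (6.30) lay below the filter level of 6.47. These genes passed the filter on the mean only through their higher values after NONO siRNA, and their control signal may be background. LRRFIP1 was 2.68-fold higher on its brightest probe set, but its 10 probe sets ranged from -0.36 to 1.47 and their mean was 0.49.

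The lowest difference was that of UHMK1, a serine/threonine kinase, which was 4.01-fold lower (9.63 to 7.62). LHFPL6 was 3.58-fold lower, and CFL2, an actin-severing cofilin, 3.21-fold lower. The matricellular growth factor gene CCN2 was 2.94-fold lower, the secreted integrin ligand EDIL3 2.79-fold, the protease inhibitor cystatin C (CST3) 2.71-fold and the collagen-binding receptor ANTXR1 2.51-fold. HLA-DMA, which helps load peptides on class II molecules, was 3.16-fold lower, and its 3 probe sets, which may hold the same probes, all gave -1.66. RPF1, a ribosome biogenesis factor, was 2.97-fold lower, the galactosyltransferase B4GALT1 2.60-fold and the GTPase-activating protein ARHGAP31 2.58-fold.

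**Figure D1:**
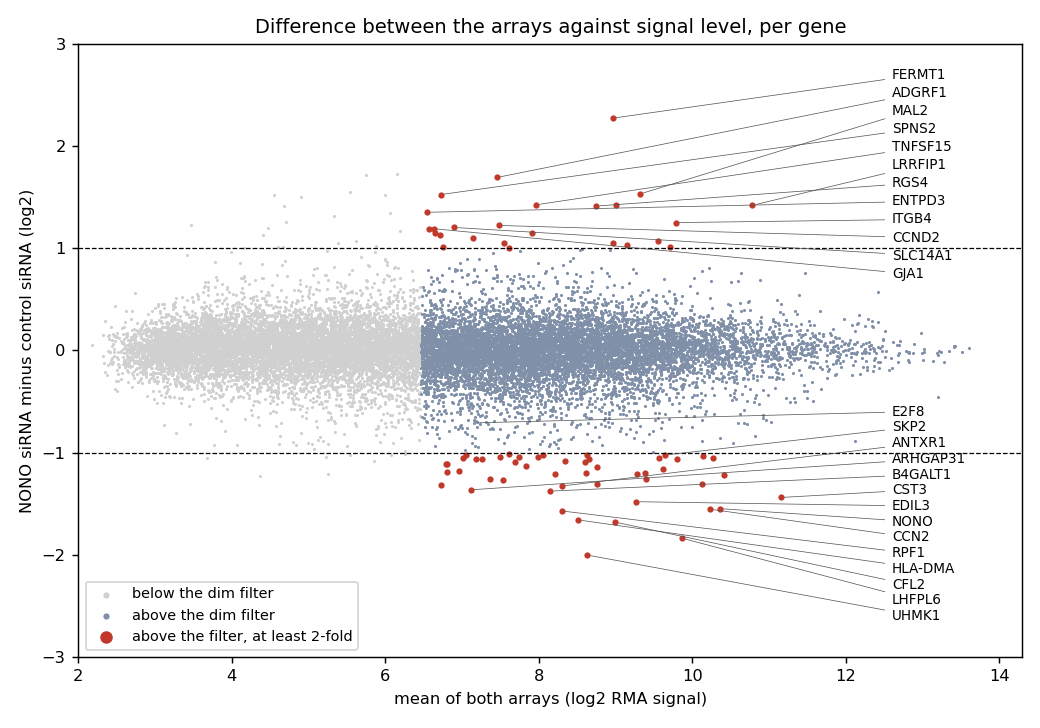
Each point is a gene, with the mean log2 signal of both arrays on the x axis and the log2 difference (NONO siRNA minus control siRNA) on the y axis; dashed lines mark 2-fold. The 25 higher and 49 lower genes past 2-fold are those above the filter, and 10 higher and 29 lower ones lie above the 75th percentile of signal. The 12 highest and 12 lowest are named, together with SKP2 and E2F8.

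Of the 20 gene lists with a percentile, 7 stood apart from random lists matched on signal, 3 higher and 4 lower. The epithelial list stood farthest out. Its 19 members above the filter, of 33 with a probe set, had a median difference of 0.383, and 0 of 10000 random lists reached that value (upper end of the central 95%, 0.105). Of these genes 6 were at least 1.5-fold higher, 0 were as much lower and 13 were within 1.5-fold. EPCAM, an epithelial cell adhesion molecule, was 2.22-fold higher, and its other probe set gave 0.97. The junction protein plakoglobin (JUP) was 1.98-fold higher, desmoplakin (DSP) and plakophilin 3 (PKP3) were both 1.66-fold higher, and keratin 19 (KRT19) was 1.60-fold higher. CLDN3 at -0.43 and KRT80 at -0.16 were the lowest members. CDH1, which encodes E-cadherin, lay below the filter and read 4.28 with control siRNA and 4.33 with NONO siRNA. The members below the filter ran from GRHL1 at -0.34 to MARVELD2 at 1.31. The median without EPCAM, JUP and DSP, left out after the data were seen, was 0.313, still above all random lists of that size.

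Markers of other cell types were measured beside the epithelial list. The 8 luminal breast markers above the filter had a median of 0.151, inside the central 95% of random lists (upper end 0.162), although without the filter the 19 luminal markers lay above it with a median of 0.175. AGR2, a secretory-pathway protein of luminal cells, was 2.14-fold higher and SPDEF was 0.49 higher, while CA12 and XBP1 differed by -0.19 and -0.08. Only CD68 of the blood cell markers passed the filter, at -0.49, and all 15 blood markers with a probe set had a median of 0.044.

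Mesenchymal and matrix genes lay on the lower side as a group, with 26 of the members above the filter lower and 13 higher. The median of 39 members above the filter, of 59 with a probe set, was -0.107, and 12 of 10000 random lists were as low. Of these genes 5 were at least 1.5-fold lower and 1 was as much higher. The lower ones were CCN2, TGFBI (2.41-fold, a matrix protein induced by TGF-beta), the collagen VI chain COL6A3 (1.97-fold), thrombospondin 1 (THBS1, 1.84-fold) and CCN1 (1.55-fold). ID1, an inhibitor of basic helix-loop-helix factors, was 1.55-fold higher. Common mesenchymal markers did not move together. COL5A1 (0.56), CDH11 (0.51), COL1A1 (0.30) and SNAI2 (0.25) were also higher, while FN1 was at -0.01 and VIM at -0.24. The repressor genes ZEB1 and ZEB2 differed in opposite directions, with ZEB1 at -0.58 and ZEB2 at 0.58, and the second probe set of ZEB2 gave 1.09. Among the 26 members above the 75th percentile of signal the median was -0.060 and inside the random range. Without CCN2, TGFBI and COL6A3, left out after the data were seen, the median of 36 genes was -0.078. That lay at the 1.1 percentile of random lists.

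Genes of S phase entry and DNA replication were slightly lower as a group. The median of 54 members was -0.130, 2 of 10000 random lists were as low, and 40 members were lower against 14 higher. Of these genes 3 were at least 1.5-fold lower and 0 as much higher. SKP2, the substrate receptor of a ubiquitin ligase that degrades the CDK inhibitor p27, was 2.03-fold lower (10.15 to 9.13). E2F8, an atypical E2F factor, was 1.64-fold lower (7.51 to 6.80), and thymidylate synthase (TYMS) was 1.54-fold lower. CCND1 at 0.35 and E2F3 at 0.24 were the highest. Without SKP2 and E2F8, which were in the list because of reports on NONO, the median of 52 genes was -0.124, at the 0.01 percentile of random lists.

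The 67 genes of G2 and mitosis had a median of -0.039, inside the random range, and 0 passed 1.5-fold in either direction. SPC25 at -0.56 and ANLN at -0.52 were the lowest, and NCAPG at 0.34 and CKAP5 at 0.24 the highest. The 30 histone cluster genes had a median of -0.104 (41 of 10000 random lists as low), with H4C2 at -0.43, H4C1 at -0.36, H4C8 at 0.35 and H2BC14 at 0.28, and 0 members past 1.5-fold. Histone genes of 1 class are near-identical in sequence, so their probe sets may share signal, and without the filter their median was -0.039, inside the range. Of 28 CDK inhibitors and p53 targets, 1 passed 1.5-fold, CCNG1 at -1.06. GADD45A followed at -0.52, ZMAT3 was highest at 0.38 and TP53INP1 read 0.22. Of 43 double-strand break repair genes, only the end-joining factor NHEJ1 passed 1.5-fold, at -0.68. EXO1 was at -0.56, RAD51C at 0.32 and H2AX at 0.25. The 27 apoptosis regulators had a median of 0.030 and 0 past 1.5-fold, from BIRC2 at -0.39 and BCL2 at -0.36 to APAF1 at 0.51 and TNFRSF10A at 0.40.

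Glycolysis and hypoxia genes were slightly higher as a group. The 37 members had a median of 0.109, and 20 of 10000 random lists were as high, with 26 members higher and 11 lower. Only EPAS1, which encodes HIF-2 alpha, passed 1.5-fold, at 1.71-fold higher. EGLN3, a HIF prolyl hydroxylase, was at 0.47, while ADM at -0.55 and DDIT4 at -0.41 were lowest. Interferon-stimulated genes were near the edge of the random range, with a median of 0.086 over 30 members and 203 of 10000 random lists as high. Of these genes 4 were at least 1.5-fold higher and 0 as much lower. IFI44 was 1.94-fold higher, IFIT1 1.75-fold, IFIT2 1.65-fold and OASL 1.60-fold, while IFI6 was at -0.55 and XAF1 at -0.21. Without IFI44 and IFIT1 the median was 0.078 and inside the range. Without the filter the median of 47 members was 0.265, above all random lists. The 36 stress response genes had a median of -0.076 (193 of 10000 random lists as low). The serine synthesis enzyme PSAT1 was 1.82-fold lower and the chaperone HYOU1 1.41-fold lower, while SEL1L at 0.34 and SLC7A5 at 0.33 were highest. This list lay inside the range under 4 of the alternatives.

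The remaining lists lay inside the random range. Of 59 splicing factors, 4 were at least 1.5-fold lower, among them the spliceosome component PRPF4 (1.81-fold) and the splicing regulator MBNL2 (1.63-fold), and PTBP2 alone was as much higher (1.70-fold), followed by SNRPD3 at 0.34. Of 34 cholesterol and fatty acid synthesis genes, 2 were at least 1.5-fold lower, the isoprenoid enzyme IDI1 (2.29-fold) and the desaturase FADS1 (1.82-fold), with LPIN1 at 0.19 and MVD at 0.16 the highest. Of 15 clock genes only CLOCK passed 1.5-fold, at 2.03-fold lower. NR1D2 was at -0.53, while BMAL1, the partner of CLOCK, was at 0.48 and BHLHE41 at 0.46. Of 20 cytokine and NF-kB genes, TNFSF15 was higher and IL11 1.63-fold lower, with IL32 at 0.33 and NFKB1 at -0.39. None of 59 respiratory chain subunits passed 1.5-fold, from SDHD at -0.45 and UQCRQ at -0.33 to UQCRC2 at 0.26 and NDUFA2 at 0.23. None of 58 ribosomal protein genes did, from RPL39L at -0.56 and RPS28 at -0.45 to RPS19 at 0.54 and RPL10 at 0.23, and processed pseudogenes can share their signal. The 17 reference genes had a median of -0.016 and 0 past 1.5-fold, with PPIA at -0.55, HPRT1 at -0.47, SDHA at 0.18 and PGK1 at 0.16.

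**Figure D2:**
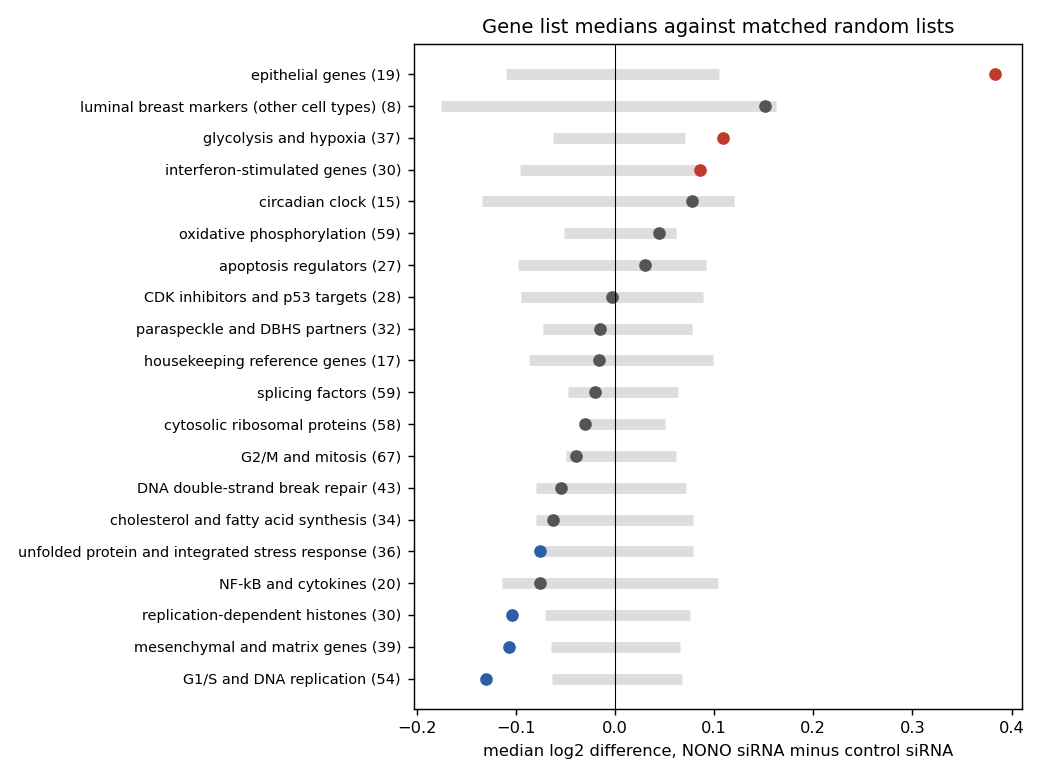
Points are the median log2 differences (x axis) of the gene lists, with the number of genes in brackets; grey bars span the central 95% of 10000 random lists matched on signal. Red points lie above and blue points below that range, and the epithelial median of 0.383 is the farthest from it.

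**Figure D3:**
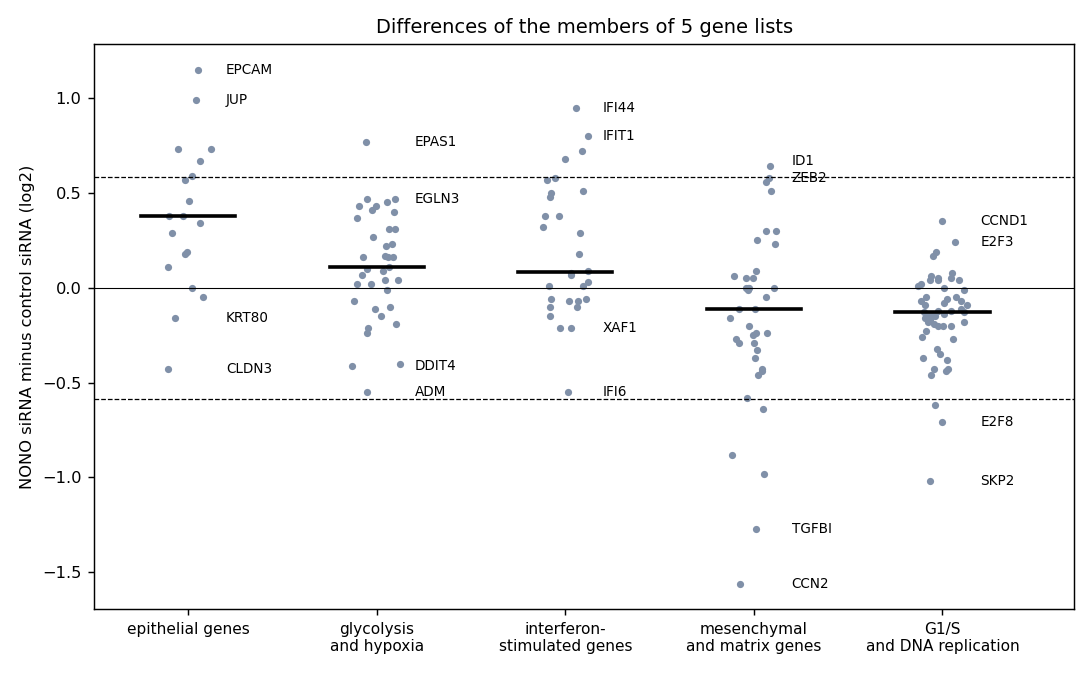
Each point is a gene of 1 of 5 lists (x axis) with its log2 difference, NONO siRNA minus control siRNA, on the y axis; black bars are list medians, dashed lines mark 1.5-fold, and the highest and lowest members are named. The epithelial median is 0.383, and the mesenchymal and S phase medians are -0.107 and -0.130.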

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

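In this part, the count for symmetric noise was chosen only after the result was seen. Probe sets without a single gene name were not used in the comparisons. Of 3360 unnamed probe sets above the filter, 25 were at least 2-fold lower after NONO siRNA and 2 at least 2-fold higher. The share past 2-fold, 0.804%, was close to the 0.8% of the named genes, so only the split by direction stood out. Of 846 probe sets that name several genes, 3 were at least 2-fold higher and 1 lower, a share of 0.473%. They were singled out because they carry differences in data outside the main measurement.

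Most of these lower unnamed probe sets have identifiers below that of the first named probe set, a block of 4203 probe sets of which 2123 passed the filter. In it 18 were at least 2-fold lower and 1 was higher, and the lowest went from 10.81 to 8.21, a difference of -2.59. A shift of the whole block is argued against, since its median was -0.0004. Measurement noise stays open: that 94.7% of the 19 were lower is the observation itself, and the probe sets need not be independent. The block may hold control probe sets of the array, and several of them may read the same few transcripts, but neither could be checked because they are unnamed here. No biological explanation was tested.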

How the results depend on the processing

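NONO stayed at -1.55 to -1.56 under every alternative run, and 0 of 309 alternative values of 103 other named genes changed sign. Little else was possible, since NONO and most of these genes have 1 probe set, which averaging cannot change. Centring shifted all genes alike by a small amount, and the loess fit moved no probe set by more than 0.028. This stability is therefore no evidence that the differences are robust. The lists of S phase genes, epithelial genes and glycolysis and hypoxia genes stood apart under every alternative run, with medians from -0.147 to -0.124, 0.289 to 0.384 and 0.088 to 0.109. Another 10 lists stayed inside the random range, and 150 of 163 alternative list medians kept their side of it. The medians after centring are among these. Centring shifts all genes alike and leaves every percentile unchanged, so their agreement was fixed in advance. The cause was not tested for the following exceptions. Without the filter, 45 genes were at least 2-fold higher, the histone and stress response medians moved inside the range (-0.039 and -0.062) and the luminal median moved above it (0.175). With the filter at the 75th percentile, which tests fewer genes, 10 genes were higher and 29 lower, the mesenchymal median moved inside (-0.060), and the medians of cholesterol and fatty acid synthesis (-0.103) and ribosomal proteins (-0.027) moved below the range. With the mean of a gene's probe sets, the stress response median (-0.071) moved inside and that of ribosomal proteins (-0.038) below. With single-probe-set genes, the interferon (0.078) and stress response (-0.073) medians moved inside, as they did with unmatched random lists at unchanged medians of 0.086 and -0.076. Leaving out IFI44 and IFIT1, chosen after seeing the data, put the interferon median (0.078) inside. A threshold of 1.5-fold gave 141 higher and 260 lower genes, and 3-fold gave 2 and 4, by construction. Centring and loess, which hardly moved any value, kept 73 and 74 of the 74 genes past 2-fold. LRRFIP1 (0.49) and ZEB2 (0.84) moved when probe sets were averaged. The blood marker list had too few members above the filter for a percentile, and the gene length comparison was not run. No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. Without detection calls, differences of genes below the filter cannot be told from background.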

Other observations

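The gene groups in this paragraph and the next were chosen after their values were seen, as was the test for RNA of another cell type. Desmosome genes, which anchor keratin filaments at cell junctions, were mostly higher after NONO siRNA. Of 8 above the filter, 7 were higher and 4 were at least 1.5-fold higher, with DSG2 at 1.97-fold beside JUP, DSP and PKP3, a median of 0.591, and EVPL at -0.12 as the lowest. JUP, DSP and PKP3 also belong to the epithelial list, so only DSG2 of these 4 was new beside it. Of 6 hemidesmosome and laminin-332 genes, 5 were higher, with ITGB4 at 1.25, LAMB3 at 0.49 and ITGA6 at 0.30, and CD151 at -0.13. ITGA6 also belongs to the mesenchymal list. Of 6 EGF family genes, the ligand genes EREG (0.79) and TGFA (0.67) were at least 1.5-fold higher, while the receptor gene EGFR was at -0.55.

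Of 25 targets and regulators of YAP and TEAD, a coactivator and the transcription factors it works through in the Hippo pathway, 19 were lower and 6 higher, with a median of -0.288. The lowest were CCN2 (-1.56), PTPN14 (-1.03), IGFBP3 (-0.85), CRIM1 (-0.72) and CCN1 (-0.64). CCN1, CCN2, ANKRD1, AXL and TGFB2 also belong to the mesenchymal list, and GADD45A to the list of CDK inhibitors and p53 targets. YAP1 itself was at -0.52, and its paralog WWTR1 at 0.54. Of 5 type 2 cystatins above the filter, 3 were higher, CST2 (1.01), CST4 (0.68) and CST1 (0.58), and 2 were lower, CST3 (-1.44) and CST7 (-0.02). CST1, CST2 and CST4 are close in sequence, so their probe sets can share signal. The splicing repressor PTBP1 was at -0.70 and its paralog PTBP2 at 0.76, a pair in which PTBP1 is known to repress PTBP2.

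The higher epithelial list is the pattern that most invites follow-up. RNA of another, epithelial cell type stays open. The 25 epithelial and luminal markers below the filter had a median of 0.116, lower than the 0.313 of the 26 above it. That comparison cannot decide, since the filter uses the mean of both arrays. Dim markers that rose, such as SPINT1 (6.20 to 6.79) and MUC1 (6.27 to 6.84), were thereby counted above it. Below it, differences ran from PRLR at -0.41 to MYB at 1.08 and MARVELD2 at 1.31. Values near background can also hide a small share (the lists share 1 gene, and MDA-MB-231 cells express many members themselves). An effect of the siRNA other than through NONO also cannot be told apart from an effect of NONO loss, since there is 1 NONO siRNA array and the labels do not say which or how many sequences it received.

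For the excess of lower genes past 2-fold, centring of the arrays stays open: the ratio of lower to higher genes was at least 2.0 after median centring or a loess fit, but the deposited arrays already shared a median and the fit moved no probe set by more than 0.028. The filter may account for part of it, as the ratio without the filter was 1.27 and 1.96 with it. With the filter at the 75th percentile the ratio was 2.9, so the split varied with signal level. Partial matches of the siRNA to other transcripts, which tend to lower their targets, were not tested, because no siRNA sequence is in the labels.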
